A study of Homo sapiens with 6 samples.

How the data were processed

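Gene expression was measured in HL-60 cells on Affymetrix arrays of 22277 probe sets, with 3 groups of 2 arrays. Per the labels' protocols, total RNA was extracted with Trizol after 24 h of treatment, and biotin-labelled cRNA was made from it by the standard protocol of the array maker. The labels call the arrays of a group biological replicates, and they do not say whether cultures were paired across groups, so p-values measure the spread between these arrays.

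The authors deposited 1 log2 expression value per probe set and array. Per the submitters' processing notes the values came from RMA, which corrects background, normalizes arrays to a common distribution and summarises the probes of a set on the log2 scale. The RMA version, and whether all 6 arrays were normalized in a single run, are not given in the sources used here. Normalization to a common distribution removes any change shared by most genes, so every difference is relative to the bulk of genes. All 133662 values carried 1 decimal, and a second deposited table held equal values (no tolerance) for all 133662. Rounding gives some genes identical values on the arrays of a group, and the variance of 47 genes was 0.

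The authors also deposited a table of regulated genes, with log2 differences of group means between DMSO and each treatment, per the file headers; fold values of that kind were used only to describe its overlap with the calls here. A further table that the authors deposited gave, for each gene ontology term, a p-value and a count of genes in the regulated and reference sets, per the file headers. Its test settings and correction are not given in the sources used here.

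Gene symbols came from the platform annotation of the probe sets, updated through a RefSeq table. Of the probe sets, 19064 had 1 gene, 1043 several, 2108 none listed and 62 were controls; symbols of 19052 were found in the RefSeq table. Each gene was represented by the probe set with the highest mean over all arrays, which left 11963 genes, and where another probe set of a gene named in the text moved under 50% as far, or the other way, its value is given near the gene's own. Probe sets with several genes or none and control probe sets stayed out of the gene counts. No genome was used, and positions are given only as cytobands of the platform annotation.

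Tests were made with R 4.3.3 and limma 3.58.1 (lmFit and eBayes, two-sided) in a single fit of all 6 arrays with 3 residual degrees of freedom, which gives the groups a common spread. P-values were adjusted by the Benjamini-Hochberg method over all genes within a comparison, with a threshold of 0.05. The standard errors printed are limma's moderated ones and intervals are at 95%. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so single genes rest on the model fitted across genes. Detection calls were not used here, so dim probe sets may carry mostly background. Array number limits precision.

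The groups, tests, 33 gene lists, alternatives and the rule for named genes were set before the data were examined. Lists held 940 entries, of which 808 were measured, and some genes stand in several lists. Each list was tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over 99 tests, with an estimated correlation and with fry as alternatives. With an estimated correlation none of the 99 tests passed (lowest adjusted p = 0.405; 6 at an unadjusted p under 0.05), against 27 with the preset; directional fry passed 4 and mixed fry 50. Fry tests whether genes of a list move, either mainly one way or in either direction, and does not compare them with other genes. Where a list's camera call is given in the text, the adjusted p with an estimated correlation stands beside it. That alternative rests on 3 residual degrees of freedom, so it could hardly pass an adjustment over 99 tests. A list that did not pass it is not thereby shown to be unshifted, and its call with the preset correlation stays uncertain.

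The named genes of each comparison were the 10 largest rises and 10 largest falls among genes that passed with non-overlapping arrays, or, where none passed, the 5 smallest p each way. To these came up to 4 passing members of each list with the largest change, or the 2 largest where none passed, and AHR, ARNT, AHRR, CYP1A1, CYP1B1, TIPARP, NQO1 and HMOX1 where measured. CAT was named because it was the only NRF2 member that fell over all genes, after its value was seen.

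The procedure was tested on simulated data with the spread of these arrays, 11963 genes and 200 changed genes in each of 20 simulations of curcumin against DMSO. It called 29.2% of genes changed 2-fold, 85.1% of those changed 4-fold and 97.0% of those changed 8-fold, and 3.47% of called genes were false. With 200 changed genes in TCDD against DMSO, in 20 further simulations of 11963 genes made after the data were seen, it called 27.9% of genes changed 2-fold, 86.0% of those changed 4-fold and 96.2% of those changed 8-fold. These rates hold for 200 changed genes. The adjustment over all genes is stricter where fewer change, so a response of few genes can be called less often, which was not simulated. In the first simulations the unchanged comparison of TCDD with DMSO gave a median of 0 calls. At an unadjusted p under 0.05, camera called 100% of shifted lists and 1.83% of unshifted ones in the curcumin simulations of 11963 genes. Lists were drawn at random there and genes varied independently, so these rates do not cover lists whose genes vary together.

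Alternatives included quantile normalization again, median centring, leaving out the dimmest 40 percent of genes, other probe set rules, another variance prior, only the 2 groups compared, stricter thresholds, the replicate number as a block and each array left out. Added after the data were seen were scaling to the hybridisation spike-ins with and without each array, scaling to the poly-A spike-ins, random digits below the rounding step with and without each array, and a crossed replicate block.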

Results

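HL-60 is an established human promyelocytic leukemia line that carries abundant granule protein transcripts and can mature along the neutrophil or monocyte path. Cultures were kept for 24 h with curcumin at 100 µM, with the dioxin TCDD at 10 nM, or with 0.5 percent DMSO, the solvent control. The sample titles give a DMSO content for the DMSO group only, so they do not show whether the treated cultures held as much. Curcumin is the thiol-reactive polyphenol of turmeric, and TCDD is a persistent agonist of the aryl hydrocarbon receptor (AHR). Each group held 2 arrays, which the labels call biological replicates, so 6 arrays entered the comparisons. RMA log2 values of 11963 genes were compared, each through 1 probe set. Array medians lay between 3.3 and 3.4, and the number of arrays limits the precision of every value. Arrays of the same group correlated across probe sets at r = 0.986 for DMSO, 0.987 for TCDD and 0.980 for curcumin. DMSO and TCDD arrays correlated with each other at 0.985 to 0.989, and curcumin arrays with the others at 0.959 to 0.970.

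The first comparison asked which transcripts differed after curcumin from the solvent control. Rises were called for 10 of 28 NRF2 antioxidant, 3 of 27 proteasome and 2 of 28 NF-kB inflammatory genes, and falls for 9 of 21 granule and promyelocyte, 10 of 24 MYC and ribosome biogenesis and 5 of 39 DNA replication genes. None of these lists passed as a whole with an estimated correlation (lowest adjusted p = 0.405 with an estimated correlation). The largest rise was that of LY96, the co-receptor of the endotoxin receptor TLR4 (cytoband 8q21.11), from 2.55 ± 0.21 to 7.15 ± 0.35 (log2, mean ± SD, n = 2 in each group). The largest fall was that of PRTN3, the granule protease proteinase 3 (cytoband 19p13.3), from 8.30 ± 0.28 to 2.90 ± 0.14. These were log2 changes of 4.60 ± 0.21 (SE; 24.3-fold, limma adjusted p = 0.000871) and -5.40 ± 0.19 (42.2-fold lower, adjusted p = 0.000336). Below the array medians, where probe sets may carry mostly background, lay LY96, HMOX1 and PIR with DMSO and PRTN3, IGLL1, GAL and ELANE with curcumin, so their changes may be understated.

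HMOX1, the heme oxygenase that degrades heme, rose by 3.45 ± 0.30 on the log2 scale (10.9-fold, adjusted p = 0.00772), and BLVRB, which reduces biliverdin, by 3.05 ± 0.27 (8.28-fold, adjusted p = 0.00873). The polyamine acetylase gene SAT1 rose by 3.35 ± 0.50, the selective autophagy receptor gene SQSTM1 by 3.15 ± 0.24 and malic enzyme ME1 by 2.85 ± 0.29. The membrane-binding annexin gene ANXA2 rose by 2.80 ± 0.20, PIR by 2.70 ± 0.20, YPEL5 by 2.60 ± 0.38 and the death receptor gene TNFRSF10B by 2.55 ± 0.25, although the other probe sets of TNFRSF10B differed by 0.00 and 0.10. The other probe set of SQSTM1 differed by 0.60, and those of ME1 by 1.20 and 0.50. Adjusted p for these 7 genes ran from 0.00507 for ANXA2 to 0.0286 for SAT1. Among the falls, IGLL1, a surrogate light chain, fell by 4.70 ± 0.15 (adjusted p = 0.000336), SERPINB10, a serine protease inhibitor, by 3.70 ± 0.42 (adjusted p = 0.0148) and the neuropeptide gene GAL by 3.60 ± 0.15 (adjusted p = 0.000809), while another probe set of GAL differed by -0.25. IFT57, of intraflagellar transport, fell by 2.50 ± 0.21 and MLC1 by 2.40 ± 0.16. The proto-oncogene MYC fell by 2.20 ± 0.17, from 10.05 ± 0.21 to 7.85 ± 0.07 (SD, adjusted p = 0.0054).

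**Figure D1:**
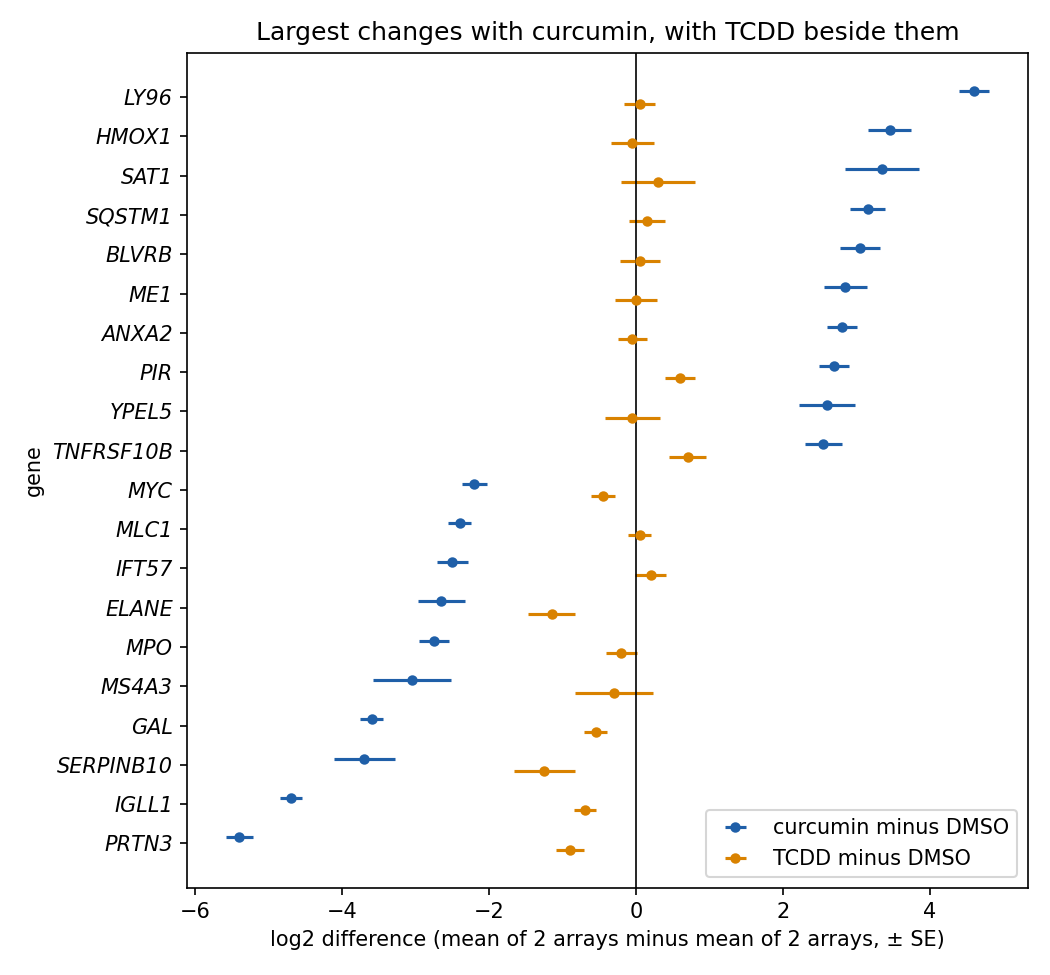
Log2 difference from DMSO (horizontal axis) of the 10 genes with the largest rise and the 10 with the largest fall after curcumin, as points with SE bars for curcumin and for TCDD (n = 2 arrays per group). Curcumin values run from 4.60 for LY96 to -5.40 for PRTN3, and the TCDD value of each gene lies nearer to 0.

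Of 28 measured members of the NRF2 antioxidant list, 10 rose, 1 fell and 17 did not pass; adjusted over the list alone, 14 rose and 2 fell. Besides HMOX1, SQSTM1, BLVRB and ME1, the cystine transporter gene SLC7A11 rose by 2.45 ± 0.15 (adjusted p = 0.00439) and the quinone reductase gene NQO1 by 1.65 ± 0.24 (adjusted p = 0.0254), with other probe sets at 0.55 and 2.25 for SLC7A11 and at 0.95 and 1.95 for NQO1. The member that fell was CAT, the catalase gene, at -1.10. The list's median was 0.63 and camera placed it above other genes (adjusted p = 2.48e-08; adjusted p = 0.537 with an estimated correlation). All 27 proteasome subunit genes had positive differences with a median of 0.60, and 3 rose, namely PSMC4 (1.10 ± 0.19), PSMD2 (1.05 ± 0.17) and PSMD1 (1.00 ± 0.15). Adjusted over the list alone, 13 proteasome genes rose (camera adjusted p = 5.42e-10; adjusted p = 0.646 with an estimated correlation). Of 28 NF-kB inflammatory genes, TNFAIP2 (2.40 ± 0.14) and the feedback inhibitor gene NFKBIA (1.55 ± 0.26) rose, which was also the count adjusted over the list alone (camera adjusted p = 0.00463; adjusted p = 0.537 with an estimated correlation). Another probe set of TNFAIP2 differed by -0.15. No member of the 10 metallothionein and zinc genes passed, by either adjustment, though all 10 values were positive (camera adjusted p = 0.00106; adjusted p = 0.552 with an estimated correlation). MT2A, a metal-binding protein gene, differed by 1.25 ± 0.30 and MT1X by 0.90 ± 0.30. Likewise, none of 27 immediate early and MAPK feedback genes passed over all genes or adjusted over the list alone, with DUSP10 at 0.75 ± 0.19 and EGR1 at 0.65 ± 0.28, and at 0.05 by its other probe set (camera adjusted p = 0.0254; adjusted p = 0.537 with an estimated correlation).

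Of 21 measured primary granule and promyelocyte genes, 9 fell and 12 did not pass, and 12 fell adjusted over the list alone. PRTN3 was joined by MS4A3 (-3.05 ± 0.53), by MPO, the myeloperoxidase gene (-2.75 ± 0.21), and by ELANE, the neutrophil elastase gene (-2.65 ± 0.32). The list's median was -0.75 (camera adjusted p = 2.21e-10; adjusted p = 0.405 with an estimated correlation; directional fry adjusted p = 0.00942). Of 24 MYC and ribosome biogenesis genes, 10 fell and none rose, and 19 fell adjusted over the list alone. Beside MYC, spermidine synthase SRM fell by 2.00 ± 0.24, and the nucleolar genes NOP16 by 1.85 ± 0.15 and MRTO4 by 1.80 ± 0.30; the other probe sets of NOP16 differed by -2.05, -0.05 and -0.10. This list had the lowest camera p of all (adjusted p = 1.74e-15; adjusted p = 0.430 with an estimated correlation; directional fry adjusted p = 0.0397). Among 39 DNA replication and G1/S genes, 5 fell and 1 rose, against 15 and 1 adjusted over the list alone (camera adjusted p = 3.42e-07; adjusted p = 0.537 with an estimated correlation). The replicative helicase gene MCM7 fell by 1.60 ± 0.16, cyclin gene CCND2 by 1.55 ± 0.20 and CDC45 by 1.15 ± 0.17, whereas the cyclin gene CCND3 rose by 1.15 ± 0.14. Other probe sets of CCND2 differed by -1.10 and -0.75. Of 37 oxidative phosphorylation genes, 4 fell, and 11 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.03e-07; adjusted p = 0.537 with an estimated correlation). They were the complex I genes NDUFV1 (-1.20 ± 0.18) and NDUFB8 (-0.95 ± 0.16), ATP5F1B of the ATP synthase (-0.90 ± 0.15) and UQCRC1 of complex III, which fell by 1.00 ± 0.18. Other probe sets of NDUFB8 differed by -0.70 and -0.30.

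Camera also placed 3 further lists below other genes. Of 48 DNA repair genes, 3 fell, and 7 fell adjusted over the list alone, among them the mismatch repair gene PMS1 (-1.80 ± 0.16) and the checkpoint kinase gene ATR (-1.45 ± 0.16, and -0.40 by its other probe set; camera adjusted p = 0.00154 for the list; adjusted p = 0.552 with an estimated correlation). Of 25 heat shock genes, 2 fell, and 4 adjusted over the list alone, with the cochaperone genes FKBP4 at -1.40 ± 0.18 and HSPE1 at -1.25 ± 0.23 (camera adjusted p = 0.0135; adjusted p = 0.776 with an estimated correlation). None of 39 mitosis and G2/M genes passed over all genes and 5 fell adjusted over the list alone, with PBK and cyclin gene CCNB1 both at -1.30 (camera adjusted p = 0.000749; adjusted p = 0.732 with an estimated correlation).

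**Figure D2:**
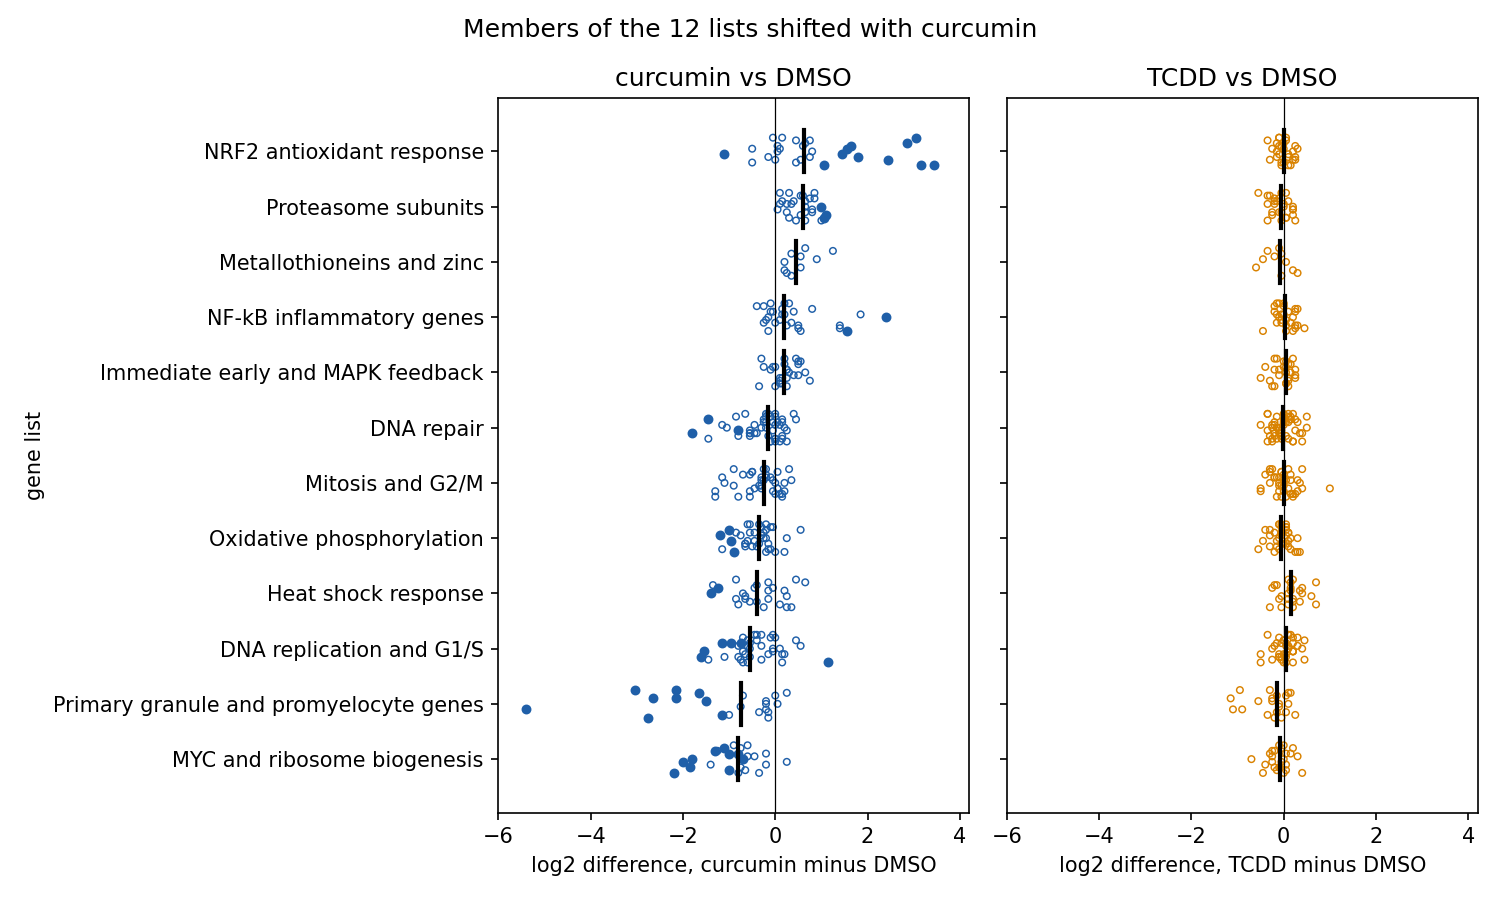
Log2 difference from DMSO (horizontal axis) of every measured member of the 12 lists that camera placed above or below other genes after curcumin (lowest adjusted p = 0.405 with an estimated correlation, so none passed that way), with curcumin on the left and TCDD on the right; filled points pass adjusted p under 0.05 over all genes, open points do not, and bars are list medians. Medians run from 0.63 for NRF2 to -0.80 for MYC and ribosome biogenesis with curcumin; the medians of the 5 upper lists were below 0 after each array was scaled to its hybridisation spike-ins, and those of NF-kB and immediate early genes after scaling to the poly-A spike-ins.

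In all, limma called 336 of 11963 genes (adjusted p under 0.05), 88 higher and 248 lower with curcumin, and 1932 genes had an unadjusted p under 0.05. Quantile normalization of the values again gave 220 higher and 314 lower. All 336 had both arrays of one group above both of the other, as did 35.5% of all genes. Between TCDD and DMSO, where no gene was called, 20.2% of all genes were separated in this way. Chance would give 33.3% without ties, and less here, since values tied by rounding counted as overlapping. Of the 336 genes, 263 differed at least 2-fold. On these arrays the hybridisation spike-ins averaged 8.99 and 9.75 with DMSO, 9.94 and 9.95 with TCDD, and 10.0 and 10.5 with curcumin. The 28S ribosomal RNA probe set of the 5' end read 4.9 and 4.6, 4.4 and 5.7, and 8.8 and 6.6 in the same order, beside the gene groups above. The 3' minus 5' difference of the beta-actin probe sets was 0.9 and 1.8, 1.7 and 2.0, and 1.6 and 2.2, lowest on DMSO replicate 1, and that of GAPDH 1.2 and 1.7, 1.3 and 1.7, and 1.4 and 1.7. Of 12 measured housekeeping genes 1 fell with curcumin, the transferrin receptor gene TFRC (-1.15 ± 0.15), against 2 adjusted over the list alone. Scaling each array to its spike-ins, an alternative added after the data were seen, moved the median difference of all genes to -0.90 and gave 16 higher and 2511 lower genes. It put the medians of NRF2 (-0.28), proteasome (-0.30), metallothionein (-0.45), NF-kB (-0.70) and immediate early genes (-0.70) below 0 and above that of all genes. That shift was -0.52 without DMSO replicate 1, which had the lowest spike-ins, with 27 higher and 418 lower genes. There the medians of NRF2 (0.0028), proteasome (0.18) and metallothionein genes (0.10) lay above 0. Without curcumin replicate 2 it was -0.65, with NRF2 (0.20) and proteasome genes (0.15) above 0 and 11 higher and 200 lower genes. Without DMSO replicate 2, curcumin replicate 1 or a TCDD array the lower genes numbered 10795, 4672 and 993. Scaling to the poly-A spike-ins, also added after the data were seen, moved all genes by -0.26 and gave 91 higher and 993 lower genes. It kept NRF2 (0.37), proteasome (0.34) and metallothionein genes (0.19) above 0, with NF-kB and immediate early genes both at -0.058. The poly-A spike-ins averaged 12.2 to 12.7 on the arrays, whose highest values were 13.2 to 13.5. Cre hybridisation spike-ins of similar brightness differed by 0.35 to 0.45, against a mean of 1.18 for the dimmer bioB probe sets. The smaller poly-A shift thus cannot be told apart from an effect of signal level.

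Leaving out any single array, or fitting only the 2 groups compared, left 0 genes past the threshold by limma (1365 to 2172 at an unadjusted p under 0.05). The values were rounded to 1 decimal, and with random digits added below the rounding step the counts were 147 without DMSO replicate 1 and 323 to 496 without another array, against 613 with all arrays. The list calls of heat shock (adjusted p up to 0.647, without curcumin replicate 2), immediate early (up to 0.270, without curcumin replicate 1) and mitosis genes (up to 0.236, without DMSO replicate 1) ended in 2 of the 6 omissions each. The other 9 list calls held in all 6, though none passed with an estimated correlation (lowest adjusted p = 0.405 with an estimated correlation). The heat shock call also ended without DMSO replicate 1 (adjusted p = 0.156), the immediate early call without DMSO replicate 2 (adjusted p = 0.219) or without dim genes (adjusted p = 0.0684) and the mitosis call without curcumin replicate 1 (adjusted p = 0.0944).

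The second comparison asked which transcripts differed after TCDD, and the AHR target genes were set out beforehand. No gene passed (limma; lowest adjusted p = 0.975; 299 genes, 2.50% of those tested, at an unadjusted p under 0.05). With no change at all a share of 0.05 would be expected there, so this share is no sign of a response. Fitting only the 2 groups compared gave 415 genes at that unadjusted threshold. CYP1A1, the cytochrome P450 gene most used as a readout of AHR activity, was at 3.25 with DMSO and 3.40 with TCDD, a log2 difference of 0.15 ± 0.19 (SE, n = 2 arrays per group) whose 95% interval ran from -0.31 to 0.61. CYP1B1 differed by 0.10 ± 0.23 (interval -0.45 to 0.65), and by 0.25, 0.25 and 0.35 in its other probe sets. TIPARP, another AHR target, differed by 0.40 ± 0.14 (interval 0.05 to 0.75, limma adjusted p = 0.975). NQO1 differed by -0.05 ± 0.24, HMOX1 by -0.05 ± 0.30 (interval -0.76 to 0.66), AHR itself by -0.20 ± 0.22 and its partner ARNT by 0.30 ± 0.23. Other probe sets differed by -0.60 and 0.05 for NQO1 and by 0.25 and -0.15 for ARNT. AHRR was not measured here.

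The 14 measured AHR battery genes had a median TCDD difference of 0.05, with 7 positive, 6 negative and 1 at 0, and none passed over all genes or adjusted over the list alone (camera adjusted p = 0.577). The 21 primary granule genes lay lower as a group, at a median of -0.15 (camera adjusted p = 0.00192; adjusted p = 0.537 with an estimated correlation), with 15 negative values. Their most negative members were ELANE at -1.15 ± 0.32 and SERPINB1, an inhibitor of granule proteases, at -1.10 ± 0.42 (-0.15 by its other probe set); none passed singly or adjusted over the list alone. The 25 heat shock genes lay higher, at a median of 0.15 (camera adjusted p = 0.0103; adjusted p = 0.761 with an estimated correlation), with CHORDC1 at 0.70 ± 0.36 and HSPH1 at 0.70 ± 0.23, and none passed by either adjustment. Scaling to the hybridisation spike-ins moved the median of all genes to -0.575 and that of the heat shock genes to -0.425. Without DMSO replicate 1 these were -0.19 and 0.056, and with poly-A spike-ins 0.027 and 0.18. Of these scalings, the first gave 5009 lower genes without DMSO replicate 2 and 0 otherwise (limma; 59 to 1000 at an unadjusted p under 0.05), and the poly-A scaling gave 1, RBM3 (adjusted p = 0.0342). The granule call ended without TCDD replicate 2, where the median of these genes stayed at -0.15. The heat shock call ended without DMSO replicate 2 or TCDD replicate 2. Each omission leaves 1 array in a group, so a lost call need not mean a smaller change.

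Among single genes with the smallest p, the transcription factor subunit gene TAF5 (1.00 ± 0.13), C1orf50 (0.90 ± 0.15), ASTE1 (0.75 ± 0.15), the integrin gene ITGAL (0.70 ± 0.14) and UBE2Z (0.70 ± 0.14) were higher with TCDD. The cold-inducible RNA-binding protein gene RBM3 (-1.40 ± 0.21), NUDT3 (-0.90 ± 0.17), CAMSAP1 (-0.80 ± 0.15), CHI3L1 (-1.20 ± 0.25) and TGM5 (-0.75 ± 0.16) were lower. Other probe sets differed by -0.25 for RBM3, by -0.40, -0.85 and -0.70 for NUDT3, by -0.20, 0.15, 0.10 and 0.25 for CAMSAP1 and by -1.15 and 0.00 for CHI3L1. Each of these 10 genes had a limma adjusted p of 0.975 and is given as a value that did not pass.

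**Figure D3:**
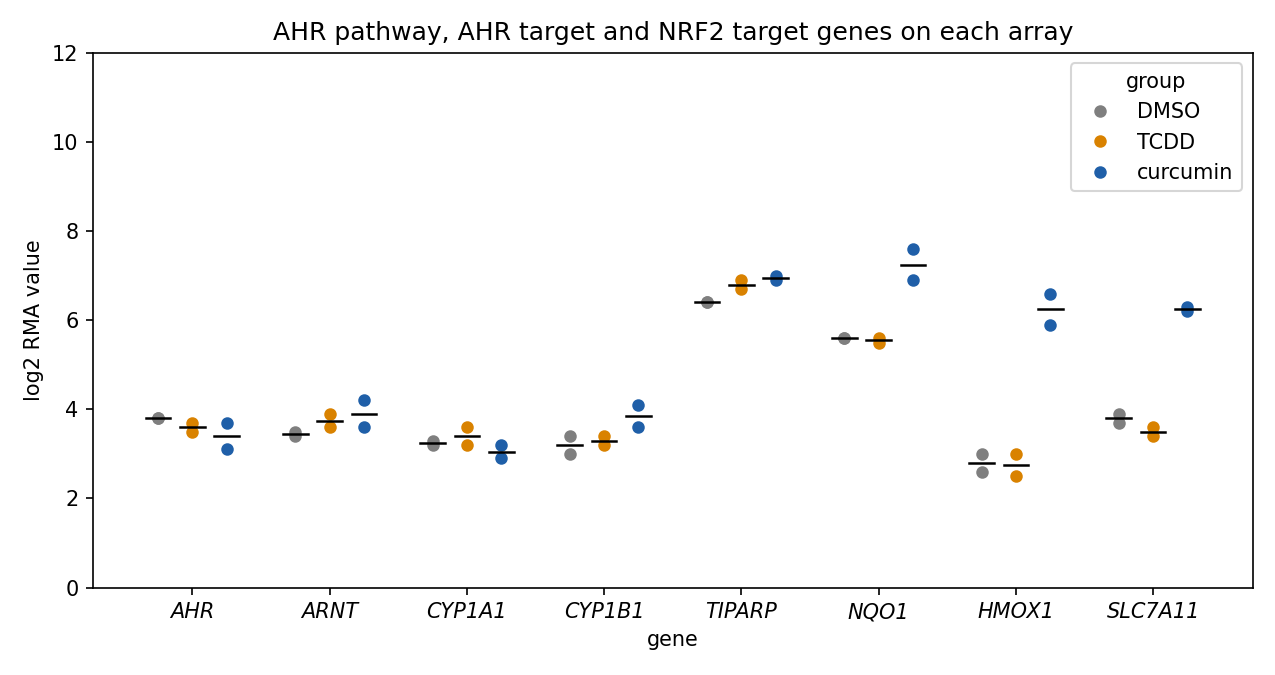
Log2 RMA value (vertical axis) of AHR, ARNT, AHR target and NRF2 target genes on each of the 6 arrays, with points for arrays and lines for group means. CYP1A1 lies at 3.25 with DMSO and 3.40 with TCDD, while HMOX1 lies at 2.80, 2.75 and 6.25 with DMSO, TCDD and curcumin.

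The third comparison set both compounds against each other. LY96 was 4.55 ± 0.21 higher with curcumin on the log2 scale (SE, n = 2 arrays per group, limma adjusted p = 0.00124), HMOX1 3.50 ± 0.30 (adjusted p = 0.00808) and SLC7A11 2.75 ± 0.15 (adjusted p = 0.00246). The quinone reductase gene NQO2 was 2.70 ± 0.15 higher (adjusted p = 0.00246) and NQO1 1.70 ± 0.24 (adjusted p = 0.0247). PRTN3 (-4.50 ± 0.19, adjusted p = 0.00106), IGLL1 (-4.00 ± 0.15), GAL (-3.05 ± 0.15) and MPO (-2.55 ± 0.21, adjusted p = 0.00725) were lower with curcumin than with TCDD. So were the pseudouridine synthase gene PUS7 (-2.20 ± 0.24), PMS1 (-2.20 ± 0.16), MYC (-1.75 ± 0.17, adjusted p = 0.00943) and CLC, which encodes the Charcot-Leyden crystal protein (-2.20 ± 0.22). Other probe sets differed by 0.50 and 2.25 for SLC7A11 and by -0.10 for GAL. CYP1A1 differed by -0.35 ± 0.19 (adjusted p = 0.457), CYP1B1 by 0.55 ± 0.23 (adjusted p = 0.314) and TIPARP by 0.15 ± 0.14 (adjusted p = 0.698), none of which passed, and the other probe sets of CYP1B1 by -0.15, 0.00 and 0.25.

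By list, 10 of 28 NRF2 genes were higher and 1 lower with curcumin than with TCDD (13 and 2 adjusted over the list alone; camera adjusted p = 2.08e-08; adjusted p = 0.537 with an estimated correlation). Of 27 proteasome genes 2 were higher, PSMC4 at 1.35 ± 0.19 and PSMD2 at 1.00 ± 0.17, and 14 adjusted over the list alone (camera adjusted p = 8.02e-12; adjusted p = 0.625 with an estimated correlation). Of 24 MYC and ribosome biogenesis genes 10 were lower, and 17 adjusted over the list alone, with SRM and NOP16 both at -1.75, and other probe sets of NOP16 at -2.00, 0.20 and 0.05 (camera adjusted p = 4.06e-14; adjusted p = 0.430 with an estimated correlation). Of 21 primary granule genes 4 were lower, and 11 adjusted over the list alone; beside PRTN3 and MPO these were RNASE2, an eosinophil-type ribonuclease gene (-1.80 ± 0.15), and the progenitor transcription factor gene MYB (-1.40 ± 0.17, and 0.00 by its other probe set; camera adjusted p = 1.03e-07 for the list; adjusted p = 0.405 with an estimated correlation). Of 25 heat shock genes 4 were lower, and 5 adjusted over the list alone, namely HSPE1 (-1.65 ± 0.23), FKBP4 (-1.50 ± 0.18), DNAJB6 (-1.10 ± 0.14) and HSPD1 (-1.05 ± 0.18) over all genes (camera adjusted p = 0.000168; adjusted p = 0.652 with an estimated correlation). The other lists called were metallothionein (camera adjusted p = 0.000672; adjusted p = 0.552 with an estimated correlation), NF-kB (0.00575; adjusted p = 0.537 with an estimated correlation) and immediate early genes (0.0135; adjusted p = 0.537 with an estimated correlation) among the higher. Lower were DNA replication (8.12e-08; adjusted p = 0.537 with an estimated correlation), oxidative phosphorylation (2.18e-07; adjusted p = 0.537 with an estimated correlation), mitosis (0.000518; adjusted p = 0.732 with an estimated correlation) and DNA repair genes (0.00435; adjusted p = 0.603 with an estimated correlation). In total 13 lists were called, the 12 of the first comparison in the same direction and cholesterol synthesis, whose 18 genes lay at a median of -0.35 with none passing by either adjustment (camera adjusted p = 0.0187; adjusted p = 0.652 with an estimated correlation).

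Limma called 290 genes between the compounds, 74 higher and 216 lower with curcumin, and 59 of the higher and 179 of the lower were also called so against DMSO, where independent lists would share 0.544 and 4.48. Both comparisons share the curcumin arrays, so the lists are not independent and any change on those arrays enters both. Over all genes both differences correlated at r = 0.881 (covariance 0.153) with the same sign for 81.4%, against a median r of 0.499 (covariance 0.0208) and 66.7% in 200 simulations of unchanged groups. Quantile normalization again gave 190 higher and 270 lower, and spike-in scaling 23 higher and 200 lower. Spike-in scaling moved the median of all genes to -0.33 and turned the medians of the immediate early (-0.18) and NF-kB genes (-0.13), while those of proteasome (0.37), metallothionein (0.25) and NRF2 genes (0.22) stayed above 0. Without curcumin replicate 1 that shift was -0.58 and the medians of proteasome (-0.13), metallothionein (-0.21) and NRF2 genes (-0.16) lay below 0, with 12 higher and 315 lower genes. Without curcumin replicate 2 it was -0.072 and none of the 5 lists lay below 0, with 22 higher and 22 lower. The lower genes numbered 602 without a DMSO array, 11 without TCDD replicate 1 and 10 without TCDD replicate 2. Poly-A scaling gave a shift of -0.29, with 73 higher and 1062 lower genes, and put immediate early (-0.14) and NF-kB genes (-0.085) below 0. Leaving out any single array, or fitting only the 2 groups compared, again left 0 genes (limma; 1901 genes at an unadjusted p under 0.05 with all arrays). With random digits below the rounding step the counts were 85.5 without TCDD replicate 1, 72 without TCDD replicate 2 and 295 to 420.5 without another array, as medians of 20 draws. The list calls of cholesterol synthesis, DNA repair and mitosis genes ended without TCDD replicate 2 (adjusted p = 0.238, 0.0654 and 0.0651), and that of cholesterol synthesis also without dim genes (adjusted p = 0.0978). Without curcumin replicate 2, those of cholesterol synthesis (0.315), DNA repair (0.111) and heat shock genes (0.113) ended, without curcumin replicate 1 those of mitosis (0.0616) and immediate early genes (0.270), and without TCDD replicate 1 that of immediate early genes (0.110).

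Across 11963 genes, which are not independent replicates, the curcumin and TCDD differences from DMSO correlated at Pearson r = 0.303 and Spearman rho = 0.321. Both differences use the same DMSO arrays, and simulated unchanged groups sharing those controls gave a median r of 0.501 (0.479 to 0.522 over 200 simulations). The covariance was 0.0261, against 0.0209 simulated (0.0195 to 0.0221), and 64.5% of genes whose differences were both other than 0 had the same sign against 66.6% simulated. The simulated groups held no curcumin effect, whereas the observed differences had an SD of 0.423 with curcumin and 0.204 with TCDD. A wider spread with curcumin lowers r, so r and the share of same signs cannot be judged against these simulations. With 2 DMSO arrays the controls could not be split with 2 in each part. With DMSO replicate 1 for curcumin and 2 for TCDD the correlation was -0.067 and the covariance -0.0079. With the reverse they were 0.092 and 0.0104. Much of the covariance of 0.0261 thus came with the shared DMSO arrays, though each of these values rests on 1 DMSO array per difference. With DMSO replicate 2 left out the correlation was 0.513. The 88 genes that rose with curcumin had a median TCDD difference of 0.10, with 57 positive and 24 negative. The 248 that fell had a median of -0.05, with 89 positive and 142 negative, the others being at 0. Against DMSO replicate 1 and replicate 2 alone these medians were 0.10 and 0.15 for the rises, and -0.15 and 0 for the falls. The genes were chosen by their difference from these same DMSO arrays, so their TCDD signs do not test a shared response. No gene was called in both comparisons against DMSO, and 0 were expected by chance since TCDD gave no call (limma; 299 at an unadjusted p under 0.05).

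**Figure D4:**
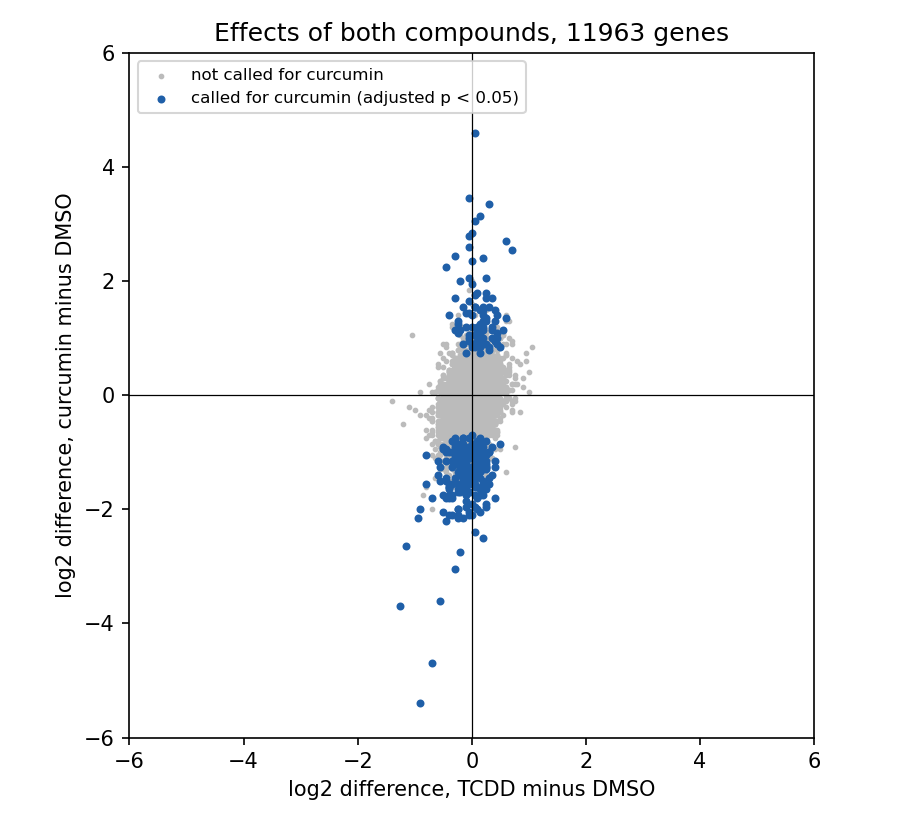
Log2 difference from DMSO with TCDD (horizontal axis) against that with curcumin (vertical axis) for 11963 genes, 1 point per gene, with the 336 genes called for curcumin in blue and both axes on the same scale. Points spread from 4.60 to -5.40 along the curcumin axis and from 1.05 to -1.40 along the TCDD axis, and both differences share the DMSO arrays.

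The authors' deposited table of regulated genes was made from these same arrays, so its overlap with the calls here describes and does not test them. That authors' deposited table held 591 probe sets, of which 584 differed from DMSO by at least 1 on the log2 scale after curcumin, 154 higher and 430 lower, and 11 after TCDD, 5 higher and 6 lower. Of the 474 genes that the authors' deposited table gave for curcumin and that were tested here, 271 (57.2%) passed here in the same direction, 446 had an unadjusted p under 0.05 and 468 had the same sign. Of the 10 genes the authors' deposited table gave for TCDD, 0 passed here by limma. The authors' deposited table of gene ontology terms for their regulated genes, which does not separate directions, held 885 terms. Among its enriched terms were rRNA metabolism with 11 of 42 reference genes (p = 3.3e-07, two-sidedness not given in the sources used here), rRNA processing with 10 of 40 (p = 3.47e-06) and ribosome biogenesis with 12 of 94 (p = 0.0002635), all as given in the authors' deposited table.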

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

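The tests of array scaling and of carried-over ribosomal RNA, and scaling to the spike-ins of either kind, were chosen after the results were seen.

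Some control probe sets, which no comparison between genes used, read higher with curcumin than with DMSO. The mean log2 difference was 2.95 for the 5' probe set of 28S ribosomal RNA, 1.75 for its middle probe set and 1.18 for the mean of the bioB spike-in probe sets, bioB being added in equal amount to every hybridisation. Other control probe sets did not, with -0.05 for the 3' probe set of 28S ribosomal RNA, -0.40 for the 5' probe set of beta-actin and -0.35 for the middle probe set of GAPDH. None of the 62 control probe sets passed the gene test (limma; 15 at an unadjusted p under 0.05). Among probe sets outside the gene counts, 32 differed between curcumin and DMSO at an adjusted p under 0.05, of which 11 had several genes (2 higher and 9 lower) and 21 had no gene listed (5 higher and 16 lower).

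The curcumin calls thus rest on arrays where spike-in and some 28S control probe sets read higher, and array scaling or ribosomal RNA carried into the labelled sample could lie behind them. Taking any single amount of at most 2 (log2) from the differences of all genes left at least 290 genes called (98 higher and 192 lower). No single shift of all genes thus removes the calls in both directions. Shifts from -0.2 to -0.05 lowered the count, to between 290 and 310, and all other shifts raised it. RMA had already brought the arrays to a common distribution, so a further single shift could hardly remove the calls. The scan therefore leaves array scaling open. The spread over genes of the difference from the TCDD mean was 0.921 times as large on curcumin replicate 1, which had the higher 28S signal, as on curcumin replicate 2, but this sets 1 array against 1 other and leaves carried-over ribosomal RNA open. After scaling to the hybridisation spike-ins, 74 of the 88 called rises and 248 of the 248 called falls kept their sign. What lies behind the spike-in differences (0.90, or 0.52 from DMSO replicate 2 alone) was not tested. Neither was how far they enter the size of single rises, or any distortion that depends on signal level. An effect of curcumin on the called genes is a hypothesis.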

How the results depend on the processing

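Both spike-in scalings, random digits below the rounding step and the crossed block were chosen after the data were seen. For curcumin against DMSO (336 genes) and curcumin against TCDD (290), the counts were 534 and 460 after quantile normalization again, where the share higher moved from 26.2% to 41.2% and from 25.5% to 41.3%. They were 565 and 480 without dim genes (fewer genes tested), 611 and 495 with the trended and robust prior, 36 and 44 at an adjusted p under 0.01, and 0 and 0 with only the 2 groups compared (limma; 1656 and 1671 at an unadjusted p under 0.05). Hybridisation spike-in scaling gave 2527 and 223, of which 0.633% and 10.3% were higher, and poly-A scaling 1084 and 1135, of which 8.39% and 6.43% were. Without single arrays the former gave 445 and 646 (DMSO replicate 1), 10810 and 646 (DMSO replicate 2), 1005 and 16 (either TCDD array), 4682 and 327 (curcumin replicate 1) and 211 and 44 (curcumin replicate 2). Centring (229 and 207), the other table, the other probe set rules and the fold threshold kept both counts within 1.5 times. Quantile normalization shared 309 genes with the 336, the trended prior 327 and spike-in scaling 264. TCDD against DMSO gave 1 gene with poly-A scaling, 5009 with hybridisation spike-in scaling without DMSO replicate 2, and 0 in every other alternative run (limma; 59 to 1000 at an unadjusted p under 0.05).

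Without single arrays the counts of both curcumin comparisons ranged from 0 to 0 (limma; 1365 to 2172 and 1384 to 2103 at an unadjusted p under 0.05). Genes with a variance of 0 rose from 47 to between 268 and 293 by rounding, and the prior degrees of freedom fell from 3.37 to between 1.35 and 1.44. With random digits, medians of 20 draws, the counts were 613 and 514 with all arrays, and ranged over the left-out arrays from 147 to 496 and from 72 to 420.5 (85.5 without TCDD replicate 1 in the latter), with prior degrees of freedom of 5.04 to 6.26.

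With the replicate number as a block the counts were 4 and 2, and with a block whose TCDD numbers were crossed 27 and 13. Deviations of same-numbered arrays correlated at -0.171 (DMSO and TCDD), 0.287 (DMSO and curcumin) and -0.128 (TCDD and curcumin), so the numbers were not taken to pair arrays. With the TCDD numbers crossed each of these would be positive. DMSO replicate 1 also correlated more with TCDD replicate 2 (r = 0.989) than with DMSO replicate 2 (r = 0.986). A grouping of arrays that the labels do not name thus stays possible, and the main fit did not model it. With the block the list calls stayed at 27.

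The 27 list calls became 0 with an estimated correlation, 4 with directional fry and 50 with mixed fry, which tests another question, and were 23 to 30 without single arrays. The correlation of effects, 0.303, was 0.349 to 0.513 with a single DMSO array (0.513 without DMSO replicate 2), and -0.067 and 0.092 with separate controls. The overlap with the authors' deposited table, 271 genes, was 446 at an unadjusted p under 0.05. Of single genes that passed on either side, CARS1 reversed under hybridisation spike-in scaling, to -0.0028, also without either TCDD array. Without DMSO replicate 2 that scaling reversed CARS1 (-0.53), PSMC4 (-0.23), PSMD2 (-0.18), PSMD1 (-0.28), CCND3 (-0.13), FTL (-0.33) and ARNT (-0.88), FPR1, NFKBIA, TUBB2A and H2BC12 (all -0.083), and with TCDD CYP1B1 (-1.06). Without curcumin replicate 1 it reversed CARS1, PSMC4 and PSMD2 (all -0.31), PSMD1 (-0.26), CCND3 (-0.058), FPR1 (-0.21), FTL (-0.16), TUBB2A (-0.0083) and H2BC12 (-0.11). Of single lists mitosis and G2/M in TCDD against DMSO, with a median of 0, took opposite directions without a DMSO array, from a median of -0.20 without replicate 2 to 0.15 without replicate 1. Over single genes and alternatives, 2547 values stayed on their side of the threshold, 1485 no longer passed, 16 newly passed and 24 reversed, and over single lists 1155, 75 and 53. A reversal was counted only where the value passed on either side. A further 70 values of 19 single gene results changed sign without passing on either side, 61 of them under hybridisation spike-in scaling. Medians of single lists changed sign 33 times, over alternatives that did not include the spike-in scalings. Apart from rounding, fewer genes or fewer arrays, the cause was not tested. Signal over background was not measured, as detection calls were not used here.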

Other observations

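The tests of dim AHR battery probe sets and of the spread between arrays were chosen after the results were seen.

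With curcumin, 3 of 13 iron handling genes changed, and 4 adjusted over the list alone (2 rose and 2 fell). HMOX1 rose as above, the ferritin light chain gene FTL rose by 1.05 ± 0.15 on the log2 scale (SE, limma adjusted p = 0.0271) and the transferrin receptor gene TFRC fell by 1.15 ± 0.15 (adjusted p = 0.0183); the list as a whole did not shift (camera adjusted p = 0.696). Among 30 apoptosis genes, TNFRSF10B rose while the survival gene BCL2 fell by 2.00 ± 0.14 (adjusted p = 0.00507) and the cytochrome c gene CYCS by 0.95 ± 0.16 (adjusted p = 0.041), with the same counts adjusted over the list alone; the other probe sets of BCL2 differed by -0.25, 0.15 and -0.05. Of 20 p53 target genes, TNFRSF10B rose and TRIAP1 fell by 1.10 ± 0.16, against 5 and 1 adjusted over the list alone (camera adjusted p = 0.0613). Of 32 ATF4 amino acid stress genes, SLC7A11 and the cysteinyl-tRNA synthetase gene CARS1 (0.90 ± 0.17, and 0.35 by its other probe set) rose, against 7 rises and 2 falls adjusted over the list alone (camera adjusted p = 0.0613). Of 39 drug metabolism genes, NQO2 (2.25 ± 0.15) and NQO1 rose, and 3 adjusted over the list alone (camera adjusted p = 0.0698). NQO1 was also the only one of 14 AHR battery genes to rise over all genes, with 3 adjusted over the list alone (camera adjusted p = 0.0689), while CYP1A1 stood at -0.20 ± 0.19, CYP1B1 at 0.65 ± 0.23 (0.10, 0.25 and 0.60 by its other probe sets) and TIPARP at 0.55 ± 0.14, none of which passed.

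Markers of mature myeloid cells went both ways with curcumin. Of 31 mature neutrophil and monocyte genes, the calcium-binding protein gene S100A8 rose by 1.75 ± 0.22 and the formyl peptide receptor gene FPR1 by 1.15 ± 0.18, while the oxidase subunit gene CYBA fell by 0.90 ± 0.16, with 4 and 1 adjusted over the list alone (camera adjusted p = 0.430). The other probe sets of S100A8 and FPR1 both differed by 0.00, and both genes, like TUBB2A, read below the array medians with DMSO. Of 13 eosinophil, basophil and mast cell markers, PRG2, the major basic protein gene, fell by 2.15 ± 0.34 and CLC by 1.95 ± 0.22, and 3 fell adjusted over the list alone (camera adjusted p = 0.459). The lactate dehydrogenase gene LDHA fell by 1.40 ± 0.16 among 30 glycolysis and hypoxia genes, against 3 rises and 4 falls adjusted over the list alone. The lamin gene LMNA (1.45 ± 0.20, with 1.20, 0.50 and 0.30 by other probe sets) and tubulin gene TUBB2A (1.15 ± 0.13) rose among 22 cytoskeleton genes, against 3 rises and 2 falls adjusted over the list alone. H2BC12 rose by 1.25 ± 0.18 among 12 histone genes, also the count adjusted over the list alone, and IFITM2 fell by 0.85 ± 0.14 among 30 interferon response genes, against 5 adjusted over the list alone. None of the erythroid (14 measured), fibroblast and epithelial (20) or lymphocyte (18) markers of other cell types passed over all genes or adjusted over the list alone in any of the 3 comparisons (limma).

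No gene was called for TCDD, including AHR targets (limma; 299 genes at an unadjusted p under 0.05, fewer than expected with no change). Small changes may be hidden by the spread between arrays or by AHR battery probe sets too dim to show one. In simulated arrays with 200 changed genes, 27.9% of genes changed 2-fold by TCDD were called, so changes of that size can be missed. With fewer changed genes the adjustment is stricter, and larger changes can be missed too. Of the measured AHR battery genes 57.1% (8 of 14) lay below the median gene in mean signal, against 49.8% of all genes (one-sided exact hypergeometric p = 0.389). Mean signal does not show whether a probe set could register a rise, so dim probe sets cannot be told apart from a lack of response. Against a large induction of CYP1A1 speaks its upper 95% limit of 0.61 on the log2 scale, unless its probe set read mostly background. A weak response of these cells to TCDD stays open and was not tested.

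The primary granule genes lay lower with TCDD as a list, at a median of -0.15. Against DMSO replicate 1 alone as the source, the median was still -0.15 against DMSO replicate 2. For a single TCDD array as the source, the higher of the medians of both TCDD arrays against the DMSO mean was -0.10, at the bound set for this test, so that one array as the source cannot be told apart from a small effect in both. The call ended without TCDD replicate 2, though the median was then still -0.15, against -0.10 without TCDD replicate 1. It was not held with an estimated correlation (camera adjusted p = 0.537), and a small effect of TCDD on these genes may be considered a hypothesis only.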
